A study of Homo sapiens with 9 samples.

How the data were processed

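RNA sequencing of total RNA from the bladder cancer line SW780 was analysed in 9 libraries, 3 each of parental cells, cells labelled as overexpressing the delta 3 form of FOXP3 and cells labelled as overexpressing full-length FOXP3. Per the labels, RNA was isolated with Trizol, libraries were made by standard Illumina protocols, and the cells labelled as overexpressing were kept in G418. The description of the series speaks of more than 1 bladder cancer line, and only SW780 was analysed here. Neither a vector-only line nor a cisplatin-treated library was analysed here.

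The deposited values were RPKM (reads scaled to the length of the gene model and to the library total) for 23368 gene symbols, made by the authors from reads aligned with TopHat to the human build hg19, per the submitters' processing notes. Versions, the read counter, the gene annotation and the strand setting were not given in the sources used here. All columns of values were used. Spreadsheet conversion had turned 28 symbols into dates, with 2 of these names occurring 2 times, and these genes were not named. The RPKM values moved in whole steps, from which the number of reads behind each was worked back. Of the 11873 tested genes, 11870 (99.97%) gave whole numbers within 0.02 reads in every library, against 0% of 300 genes with jittered values. Library totals ran from 28.6 to 34.8 M reads, and 1 read in a gene model of 1 kb was worth 0.0287 to 0.0350 RPKM. The build hg19 was not at hand, so no coordinates were used. GENCODE release 29, on a later build, served only for the exon lengths of FOXP3.

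Genes with at least 1 RPKM in at least 3 of the 9 libraries were tested. log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust settings), with group as the only factor and all 9 libraries in 1 fit. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with adjusted p under 0.05 as the threshold. Fold changes are on the scale of RPKM + 1, a ± after a log2 fold change is its standard error, and a ± after RPKM is the standard deviation of 3 libraries. The labels do not say whether replicates were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical. Nor do they say how many lines were derived for each construct. If each group is 1 line, even separate cultures cannot tell an effect of the construct from a difference between lines.

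Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. The 34 lists were written from general knowledge, and 31 had at least 5 tested members. All 1067 list members were matched to the table (100%). Camera was also run with an inter-gene correlation estimated from the data, which is the stricter test. For each list the members past the threshold were counted, first adjusted over all tested genes and then adjusted over the list alone.

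Genes were named by a rule. For each contrast it took the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, a mean of at least 5 RPKM in the higher group and groups that did not overlap. For each list it took up to 4 members in order of adjusted p, and for shared changes the 6 genes per direction with the largest smaller fold change. Uncharacterised loci, small RNAs, ribosomal protein genes and histone genes were counted but not named, and FOXP3 was always given. Some genes picked by the rule are not reported here. Grouping, tests, lists, the naming rule and most alternative settings were chosen before the data were examined.

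Changes shared by the delta3-labelled and full-length groups were set against 1000 simulated pairs of unchanged groups that shared the parental libraries, and against 100 full simulated fits. Alternative settings covered the pseudocount, the expression filter, quantile and median-ratio scaling, the variance prior, the libraries in the fit, a replicate block, library weights, and each library left out in turn. Settings chosen after seeing the data were limma-voom on the recovered reads, averaging close replicates, leaving out all libraries numbered 1, the gene lists without parental replicate 1, and a replicate block for the delta3-labelled and full-length groups alone. The labels do not say that a replicate number marks a shared day or batch. In their deviations from the group means, libraries of the same number correlated at r = 0.437, 0.12 and 0.493 between the libraries labelled delta3 and the full-length ones, and at r = -0.223 to 0.165 with the parental libraries. The numbers were therefore taken to pair samples only between the delta3-labelled and full-length groups, from the data alone, and the pairing of replicates 2 and 3 is weak. Delta3 replicate 2 correlated as much with full-length replicate 3 (r = 0.127), and delta3 replicate 3 correlated with full-length replicate 2 at r = 0.354. No scaling moved the median log2 fold change of all genes by over 0.1.

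The procedure was tested on simulated data with changes of known size. Of the genes moved by 0.5, 1 and 2 log2 units, 28.4%, 89.6% and 98.5% were called, 5 of 149 calls were false, and a contrast without change gave 0 calls. A moved list gave a camera p of 4.34e-40 and an unmoved list 0.43. Noise in these simulated data was drawn independently for each gene and library, without correlated genes, close replicates or an outlying library. These rates therefore need not hold in the real libraries. Fits simulated instead from the observed deviations gave up to 2947 same-sign calls without any change. Computation outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.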

Results

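SW780, an established human bladder cancer cell line, was profiled by RNA sequencing in 3 groups of 3 libraries. The groups were the parental line, cells labelled as overexpressing the delta 3 form of FOXP3 and cells labelled as overexpressing full-length FOXP3. FOXP3 is a forkhead transcription factor best known as the lineage factor of regulatory T cells. Per the labels, the cells labelled as overexpressing were kept in G418, a selection drug, and a line carrying an empty vector was not analysed here. The series concerns the delta 3 isoform in bladder cancer and names differentiation and cisplatin resistance as its themes, and no cisplatin-treated library was analysed here. The libraries labelled delta3 and the full-length ones were each compared with the parental line and with each other. Reads worked back from the deposited values came to 28.6, 29.6 and 31.0 M for the parental libraries, 28.9, 30.3 and 33.1 M for those labelled delta3, and 33.3, 34.8 and 32.2 M for the full-length libraries. At these depths 1 read in a gene model of 1 kb was worth 0.0287 to 0.0350 RPKM, and 11873 genes were tested.

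The 9 libraries separated by labelled group on the first 2 principal components, which held 43.7% and 27.7% of the variance of log2(RPKM + 1). The third component, with 16.7%, set parental replicate 1 apart from parental replicates 2 and 3. Across genes, parental replicate 1 correlated with the other parental libraries at r = 0.959 and 0.960 and with the libraries of the other groups at r = 0.952 or less, and genes are not independent replicates. In parental replicate 1, 675 genes lay at least 2-fold from the mean of parental replicates 2 and 3, against 10 genes between replicates 2 and 3. Replicate 1 also lay furthest in the other groups, with 115 against 32 genes in the libraries labelled delta3 and 93 against 13 genes in the full-length ones. Among the genes of parental replicate 1, TAGLN, an actin-binding protein of smooth muscle, stood at 289 RPKM in parental replicate 1 and at 13.8 and 13.9 RPKM in replicates 2 and 3. UPK2, a uroplakin of the urothelial surface, stood at 10.6 RPKM against 159 and 162 RPKM. The chi-square per degree of freedom on recovered reads was 1.46 between parental replicates 2 and 3, 9.86 between those labelled delta3 and 5.43 between the full-length ones, and 43.3 or more between replicate 1 and the others of any group. Repeat libraries of 1 sample can exceed 1 as well, so these values do not show whether replicates 2 and 3 were separate cultures, and all 9 libraries were counted as labelled.

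**Figure D1:**
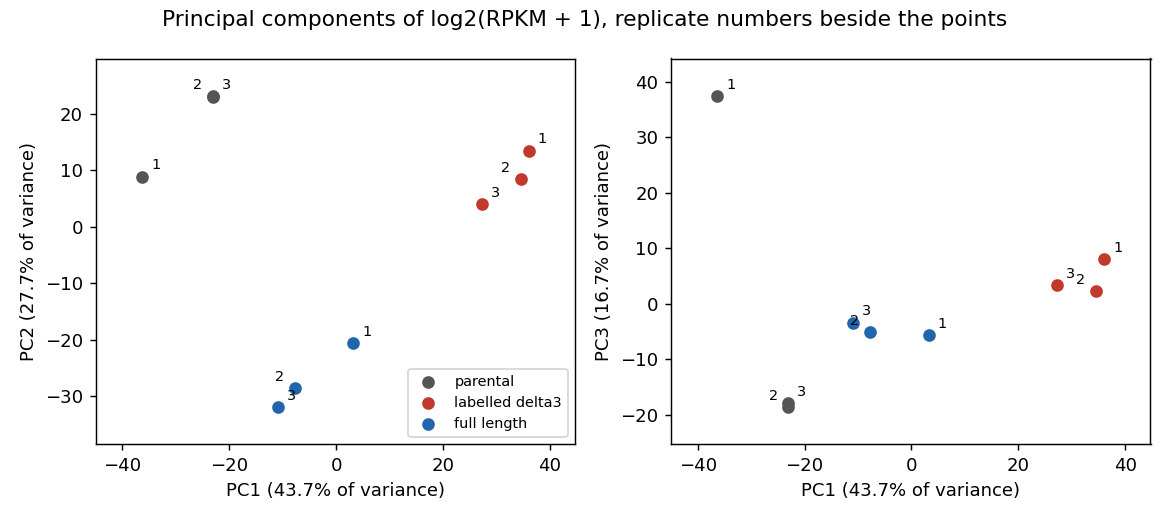
Each point is 1 library placed by principal components of log2(RPKM + 1) over the 11873 tested genes, with its replicate number beside it and its colour giving the labelled group. Components 1 and 2 separate the 3 groups, and component 3, with 16.7% of the variance, sets parental replicate 1 apart from parental replicates 2 and 3.

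FOXP3 was examined first, because it tests the labels. Its level was 0.209 ± 0.106 RPKM in the parental libraries (SD, n = 3), 0.355 ± 0.0318 RPKM in the libraries labelled delta3 (n = 3) and 85.6 ± 2.91 RPKM in the full-length libraries (n = 3). In recovered reads this was 8, 13 and 24 reads in the parental libraries, 26, 23 and 29 reads in those labelled delta3, and 6959, 6830 and 6650 reads in the full-length libraries. The full-length libraries rose over the parental ones by 6.17 ± 0.09 on the log2(RPKM + 1) scale (limma adjusted p = 3.12e-09). In the libraries labelled delta3 FOXP3 did not pass the test against the parental line, with a log2 fold change of 0.17 ± 0.09 (adjusted p = 0.196) and a ratio of mean RPKM of 1.70. Against the full-length libraries those labelled delta3 were lower, with a log2 fold change of -6.00 (adjusted p = 3.98e-09), and held 0.414% of their mean RPKM. The values are per gene and do not separate isoforms. The gene model counted was 2382 nt long, the length of 1 annotated transcript of 12 exons, in which exon 3 takes up 4.41% and the longest internal exon 9.74%. For these reasons the group is called the libraries labelled delta3 throughout, and no direction drawn from it rests on a measured rise of FOXP3.

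**Figure D2:**
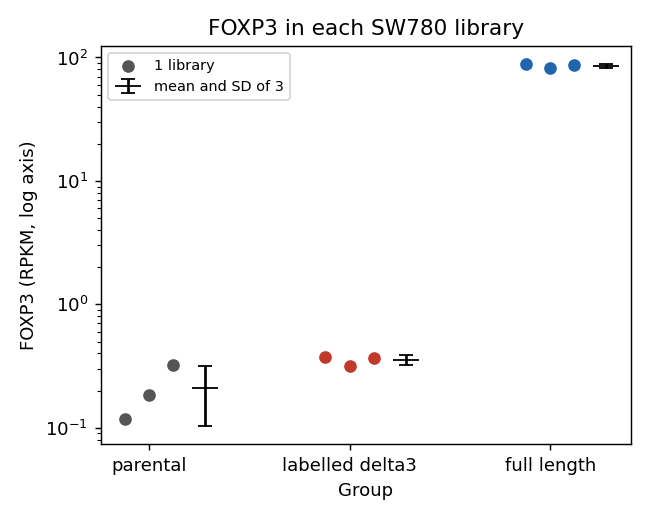
FOXP3 in RPKM on a log axis, with 1 point per library and the mean and SD of the 3 libraries beside each group. The full-length libraries lie between 82.3 and 87.8 RPKM, and none of the 6 other libraries lies above 0.378 RPKM.

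The comparison of the libraries labelled delta3 with the parental line asks what distinguishes cells carrying this construct label. The largest rises were in ALPP, placental alkaline phosphatase, from 2.603 ± 0.72 to 116 ± 20.5 RPKM (SD, n = 3), and in BPIFB1, a secreted airway protein, from 0.332 ± 0.253 to 40.4 ± 8.63 RPKM. MUC1, a transmembrane mucin, rose from 1.65 ± 1.2 to 61.8 ± 11.6 RPKM. FXYD4, PI3, LYPD2, ALPPL2, CEACAM6 and L1CAM followed, with rises of 23.9, 22.7, 22.4, 21.8, 15.8 and 12.6-fold on the scale of RPKM + 1. PI3 encodes the elastase inhibitor elafin, and CEACAM6 and L1CAM are adhesion molecules. The largest falls were in KRT13, a keratin of stratified epithelia, from 407 ± 185 to 35.9 ± 18.8 RPKM, and in MT2A, a metallothionein, from 239.5 ± 223 to 17.2 ± 7.15 RPKM. CAPNS2, EEF1A2, IFI27, HAS3, IGFL1, KRT6A, CXCL1 and DFNA5 fell by 9.43 to 5.64-fold. For these genes limma adjusted p ran from 3.68e-05 for BPIFB1 to 0.00387 for IFI27. Without parental replicate 1 the log2 fold changes of MT2A, FXYD4 and PI3 were -2.68, 3.78 and 3.84, against -3.40, 4.58 and 4.51 with it, and those of IFI27 and IGFL1 were -3.66 and -3.42, against -2.93 and -2.81. ALPP with ALPPL2, CEACAM6 with CEACAM3, MT2A and KRT6A have close paralogs, so their split of reads is uncertain.

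Gene lists fixed beforehand were then compared. Basal and squamous genes fell in the libraries labelled delta3: of 29 tested members 15 fell, 1 rose and 13 did not pass (18 and 2 adjusted over the list alone), with a median log2 fold change of -0.997. Its camera test gave adjusted p = 0.000246, and adjusted p = 0.836 with an estimated correlation. DSC3, a desmosomal cadherin, SFN, or stratifin, KRT17, a basal keratin, and TP63, the transcription factor of basal epithelial cells, changed by -1.23, -1.87, -2.34 and -1.94 log2 units. The 1 member that rose was PI3, which is among the largest rises given above. Luminal urothelial genes rose, with 12 of 29 higher, 2 lower and 15 not passing (13 and 2 adjusted over the list alone) and a median of 0.42 (camera adjusted p = 0.0112; adjusted p = 0.977 with an estimated correlation). The simple-epithelium keratins KRT18 and KRT8 rose by 1.11 and 1.005 log2 units, ELF3, an epithelial ETS factor, by 1.73 and TRIM31, a RING-finger protein, by 2.01. This list moved with parental replicate 1, in which its median lay 0.92 log2 units below the mean of parental replicates 2 and 3 (difference -0.92), and without that library it did not pass (median 0.35, 11 higher and 8 lower, adjusted p = 0.532).

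Epithelial junction genes rose in the libraries labelled delta3, with 13 of 32 higher, 2 lower and 17 not passing (13 and 3 adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.836 with an estimated correlation). The tight-junction claudins CLDN4 and CLDN3 rose by 0.82 and 1.61 log2 units and the desmosomal plakophilin PKP2 by 1.02, while desmoplakin, DSP, fell by 1.75. Of 20 tested genes of protein folding in the endoplasmic reticulum, 10 rose, 1 fell and 9 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 0.00422; adjusted p = 0.746 with an estimated correlation). XBP1, the transcription factor of the unfolded protein response, rose by 0.64 log2 units and the chaperone HSP90B1 by 0.36, and the disulfide isomerase PDIA6 fell by 0.38. Cholesterol synthesis genes rose, with 5 of 24 higher, 0 lower and 19 not passing (5 and 0 adjusted over the list alone; camera adjusted p = 0.00689; adjusted p = 0.836 with an estimated correlation). Its regulator SREBF2 rose by 0.71 log2 units and the squalene synthase FDFT1 by 0.59, a call lost without delta3 replicate 2 (adjusted p = 0.0504). Of 8 tested replication-dependent histone genes, which are counted but not named, 5 rose, 1 fell and 2 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.00689; adjusted p = 0.836 with an estimated correlation).

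Genes of ATF4 and the amino acid stress response fell, with 14 of 31 lower, 3 higher and 14 not passing (15 and 3 adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.426 with an estimated correlation). The amino acid transporter subunits SLC3A2 and SLC7A5 changed by -0.76 and -1.63 log2 units and the aminotransferase GPT2 by -0.92. Of 14 tested genes that have been named as FOXP3 targets in epithelial cells, 7 fell, 1 rose and 6 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.0312; adjusted p = 0.604 with an estimated correlation). VEGFA, an angiogenic factor, MYC, the growth-promoting transcription factor, TGFB1, a cytokine, and SATB1, a chromatin organizer, changed by -1.45, -0.78, -1.34 and -0.53 log2 units, in libraries where no rise of FOXP3 itself was shown. VEGFA is also in the hypoxia list, and TGFB1 and SATB1 in that of regulatory T cell genes. Hypoxia and glycolysis genes fell, with 9 of 32 lower, 3 higher and 20 not passing (11 and 3 adjusted over the list alone; camera adjusted p = 0.0492; adjusted p = 0.836 with an estimated correlation). The glycolytic enzymes ENO1 and GPI fell by 1.19 and 0.80 log2 units and the lactate transporter SLC16A3 rose by 2.53. Ribosomal protein genes, many of which have processed pseudogenes, fell with 18 of 58 lower, 2 higher and 38 not passing (19 and 2 adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.982 with an estimated correlation).

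In all, 4048 of 11873 genes passed between the libraries labelled delta3 and the parental line, 1824 higher and 2224 lower (2068 and 1921 with median-ratio scaling), and 733 of these by at least 2-fold (446 higher, 287 lower). The groups did not overlap for 47.6% of genes, where chance gives 10% if all libraries are independent, and more if replicates 2 and 3 are not. Without delta3 replicate 2 the count was 2580, and with replicates 2 and 3 of each group averaged and counted as 1 library, a setting chosen after seeing the data, it was 755. Without parental replicate 1, the basal, endoplasmic reticulum and histone lists still passed (adjusted p = 0.000216, 0.00063 and 0.0022). The other 7 lists did not, though all kept the sign of their median. The median of ATF4 was -0.37 without it against -0.33 with it (adjusted p = 0.104), that of the FOXP3 targets -0.42 against -0.34 (adjusted p = 0.0952) and that of the luminal list 0.35 against 0.42. Junctions stood at 0.18 against 0.34 (adjusted p = 0.0952), cholesterol synthesis at 0.12 against 0.29 (adjusted p = 0.0995), hypoxia at -0.15 against -0.36 (adjusted p = 0.633) and ribosomal proteins at -0.01 against -0.14 (adjusted p = 0.835). With fry, a test of each list by itself, the luminal, junction, cholesterol and ribosomal lists did not pass (adjusted p = 0.178, 0.0837, 0.126 and 0.149).

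Full-length FOXP3 cells were compared with the parental line to show what accompanies a raised FOXP3 mRNA. Besides FOXP3, the largest rises were in CEACAM6, from 99.3 ± 36.4 to 1694 ± 25.2 RPKM (SD, n = 3), in S100A4, a calcium-binding protein, from 17.9 ± 11.9 to 225 ± 126 RPKM, and in F2R, the thrombin receptor, from 0.714 ± 0.695 to 19.96 ± 1.75 RPKM. H19, an imprinted non-coding RNA, rose from 47.3 ± 4.61 to 625 ± 213 RPKM. The cytochrome P450 genes CYP2B6 and CYP2S1, with PKNOX2, CEACAM3 and CST1, rose by 7.71 to 6.19-fold on the scale of RPKM + 1. Among the 10 largest falls were those of the chemokines CXCL1, from 66.4 ± 32.6 to 1.04 ± 0.208 RPKM, and IL8, from 44.1 ± 3.17 to 2.74 ± 0.798 RPKM, and of the interferon-induced IFI27, from 59.5 ± 37 to 1.63 ± 0.658 RPKM. MSN, a membrane linker of actin, LDOC1, MYL9, a myosin light chain, KRT13, the antiviral MX1 and EEF1A2 fell by 14.7, 11.7, 10.7, 10.7, 7.48 and 7.31-fold. S100A8, a calgranulin, passed narrowly, with a log2 fold change of -3.42 ± 1.08 (adjusted p = 0.0459). It stood at 0.334, 35.6 and 33.3 RPKM in the 3 parental libraries, and its call was lost when any 1 of the 8 libraries other than parental replicate 1 was left out (adjusted p = 0.0611 to 0.139). Without parental replicate 1, 2 or 3 its log2 fold change was -4.999, -2.61 or -2.66. Without parental replicate 1 MYL9, which stood at 80.7 RPKM there and at 7.60 and 7.14 RPKM in the other parental libraries, changed by -2.33 log2 units against -3.42 with it. The log2 fold changes of S100A4, IFI27 and MX1 were 2.999, -4.99 and -3.75 without that library, against 3.77, -4.26 and -2.90. Among the 19 genes other than S100A8, limma adjusted p ran from 3.12e-09 for FOXP3 to 0.0117 for MYL9.

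Interferon response genes fell in the full-length libraries: of 52 tested members 32 fell, 0 rose and 20 did not pass (36 and 1 adjusted over the list alone), with a median log2 fold change of -0.67. Its camera test gave adjusted p = 6.17e-11, and adjusted p = 0.437 with an estimated correlation. IFIT1 and OASL, induced antiviral effectors, changed by -2.69 and -1.83 log2 units, the exonuclease ISG20 by -1.78 and IFI35 by -1.65. Genes of NF-kB signalling and inflammatory cytokines fell, with 19 of 32 lower, 0 higher and 13 not passing (21 and 0 adjusted over the list alone; camera adjusted p = 8.99e-08; adjusted p = 0.437 with an estimated correlation). The acute-phase gene SAA1, the growth factor CSF1, IL8 and CXCL1 changed by -2.23, -1.27, -3.61 and -4.90 log2 units. Of 17 tested genes of MHC class I and II presentation, 9 fell, 0 rose and 8 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 0.00505; adjusted p = 0.437 with an estimated correlation). The class I genes HLA-F and HLA-C, which share reads with each other, fell by 0.73 and 0.56 log2 units. Most class II members, among them HLA-DRA, HLA-DRB1, HLA-DPA1 and HLA-DPB1, missed the expression filter, so this list speaks mainly for class I. In parental replicate 1 the interferon list had a median log2 difference of -0.28 from replicates 2 and 3, and the call held without that library (adjusted p = 3.31e-11).

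Amino acid stress genes under ATF4 fell in the full-length libraries, with 15 of 31 lower, 0 higher and 16 not passing (17 and 1 adjusted over the list alone; camera adjusted p = 1.16e-05). This was the only list that passed with an estimated correlation in any of the 3 contrasts (adjusted p = 0.0447). The correlation estimated for it was -0.0201, under the preset 0.01, against 0.225 for the interferon list and 0.496 for the histones. Its pass therefore rests in part on a low estimate from 9 libraries. Asparagine synthetase, ASNS, changed by -1.31 log2 units, SLC3A2 by -1.08, the stress-induced DDIT4 by -1.55 and CBS, an enzyme of cysteine synthesis, by -2.20. Histone genes rose, with 7 of 8 higher, 0 lower and 1 not passing (7 and 1 adjusted over the list alone; camera adjusted p = 9.26e-05; adjusted p = 0.444 with an estimated correlation). Mismatch repair genes rose, with 6 of 16 higher, 0 lower and 10 not passing (8 and 0 adjusted over the list alone; camera adjusted p = 0.00505; adjusted p = 0.444 with an estimated correlation). RFC5, a replication factor subunit also in the excision repair list, rose by 0.40 log2 units, and its call was lost without parental replicate 2 or 3 or full-length replicate 2 or 3 (adjusted p = 0.064 to 0.0676). The mismatch members PCNA, LIG1, POLD1 and RFC1 to RFC4 are in the excision repair list as well. Homologous recombination and Fanconi pathway genes rose, with 11 of 46 higher, 1 lower and 34 not passing (11 and 1 adjusted over the list alone; camera adjusted p = 0.00679; adjusted p = 0.535 with an estimated correlation). The Fanconi ubiquitin-conjugating enzyme UBE2T, the checkpoint kinase CHEK1 and RMI1 rose by 0.57, 0.74 and 0.80 log2 units.

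Endoplasmic reticulum folding genes rose in the full-length libraries, with 7 of 20 higher, 1 lower and 12 not passing (9 and 1 adjusted over the list alone; camera adjusted p = 0.00679; adjusted p = 0.5 with an estimated correlation), among them the chaperone HSP90B1 (0.57 log2 units) and the co-chaperone DNAJC3 (0.66). Hypoxia and glycolysis genes fell, with 7 of 32 lower, 0 higher and 25 not passing (7 and 0 adjusted over the list alone; camera adjusted p = 0.0201; adjusted p = 0.699 with an estimated correlation). NDRG1 changed by -1.36 log2 units and the aldolase ALDOC by -1.12. Ribosomal protein genes fell, with 15 of 58 lower, 1 higher and 42 not passing (15 and 1 adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.936 with an estimated correlation). Differentiation lists did not pass here. Of 29 basal genes 7 fell, 2 rose and 20 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.195). KRT17, the laminin LAMB3 and DSC3 fell by 2.41, 0.74 and 0.81 log2 units, and the basal keratin KRT5 rose by 1.30. Of 29 luminal genes 4 rose, 1 fell and 24 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.376), KRT18 and KRT8 rising by 0.80 and 0.78 log2 units. The genes named as FOXP3 targets in epithelial cells did not pass as a list either. Of 14 tested, 5 fell, 1 rose and 8 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.297). The chemokine CCL5, MYC and VEGFA fell by 1.71, 0.45 and 0.58 log2 units and SKP2, an F-box protein of the cell cycle, rose by 0.57.

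In all, 3190 of 11873 genes passed between the full-length and the parental libraries, 1385 higher and 1805 lower, and 350 by at least 2-fold (170 higher, 180 lower). The groups did not overlap for 46.6% of genes, where chance gives 10% if all libraries are independent, and more if replicates 2 and 3 are not. Leaving out parental replicate 2 or 3 or full-length replicate 2 or 3 gave 1941, 1934, 1704 and 1733 genes, and averaging replicates 2 and 3 of each group gave 94. Without parental replicate 1, 8 of the 10 lists still passed, hypoxia and ribosomal proteins did not (medians -0.12 and -0.05 against -0.27 and -0.14, adjusted p = 0.574 and 0.344), and mesenchymal genes and YAP/TEAD targets passed as higher (adjusted p = 0.00139 and 0.0201, against 0.171 and 0.637 with it). With fry the hypoxia and ribosomal lists did not pass (adjusted p = 0.0595 and 0.203).

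**Figure D3:**
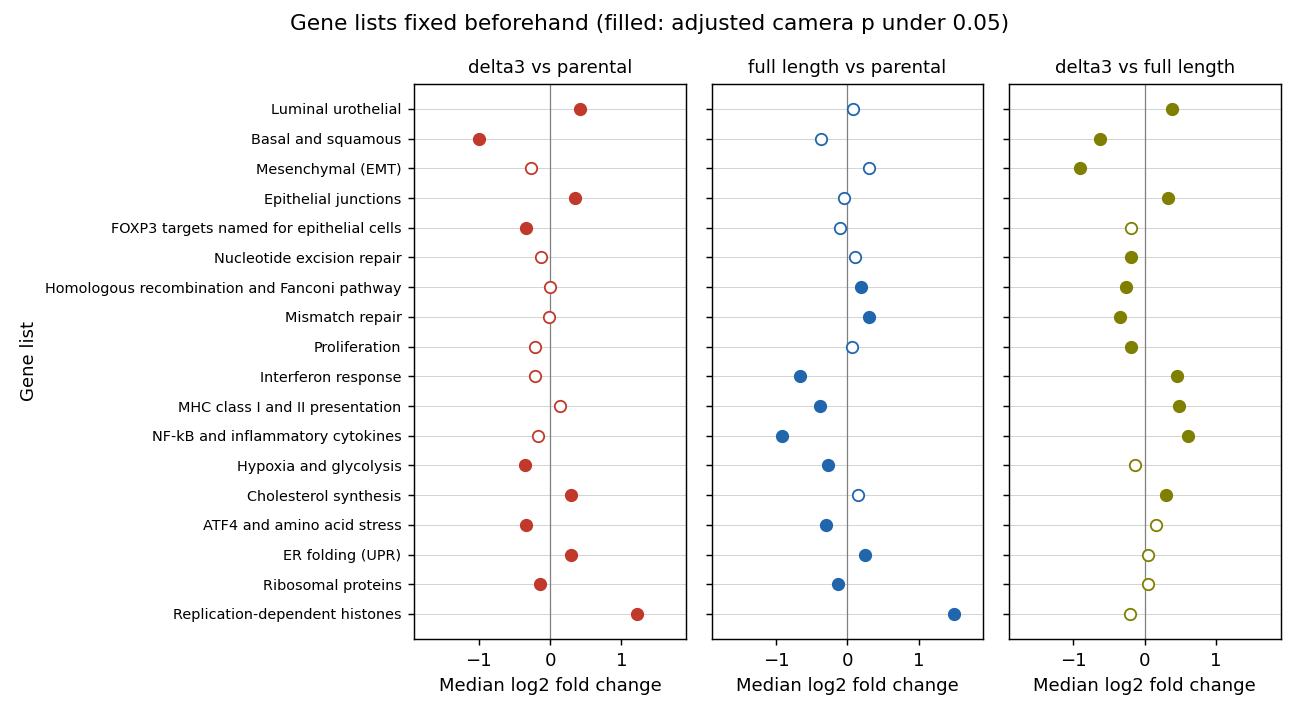
Median log2 fold change of the tested members of each list that passed in at least 1 contrast, with filled points for a camera adjusted p under 0.05. Interferon response, MHC and NF-kB lists lie below 0 in the full-length against the parental libraries and above 0 in the libraries labelled delta3 against the full-length ones.

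The libraries labelled delta3 were compared directly with the full-length ones, which asks where these groups differ from each other and does not use the parental levels. FXYD4, PI3, MUC1, ALPP, BPIFB1, LYPD2 and L1CAM were again among the most raised in the libraries labelled delta3, by 33.8 to 15.3-fold on the scale of RPKM + 1. LDOC1 stood at 22.55 ± 1.1 against 0.606 ± 0.351 RPKM (SD, n = 3) and ASS1, argininosuccinate synthase, at 79.5 ± 25.9 against 4.53 ± 1.57 RPKM. After FOXP3, the genes most raised in the full-length libraries were H19, at 625 ± 213 against 30.2 ± 31.7 RPKM, whose log2 fold change was -5.55 without delta3 replicate 1 against -4.75 with it, and CYP2B6, at 27.0 ± 7.31 against 0.918 ± 0.488 RPKM. PADI3, an arginine deiminase of hair and skin, KRT6A, TRNP1, CYP2B7P1, a pseudogene neighbour of CYP2B6 that can share its reads, and LBH followed, at 8.50, 7.79, 6.13, 6.10 and 4.75-fold. The collagen gene COL17A1 and MT2A were also higher in the full-length libraries, by 5.27 and 4.82-fold (adjusted p = 0.0223 and 0.0257). Both calls were lost when delta3 replicate 1 or 2 or full-length replicate 2 or 3 was left out (adjusted p = 0.0705 to 0.0873 for COL17A1 and 0.0811 to 0.0992 for MT2A).

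**Figure D4:**
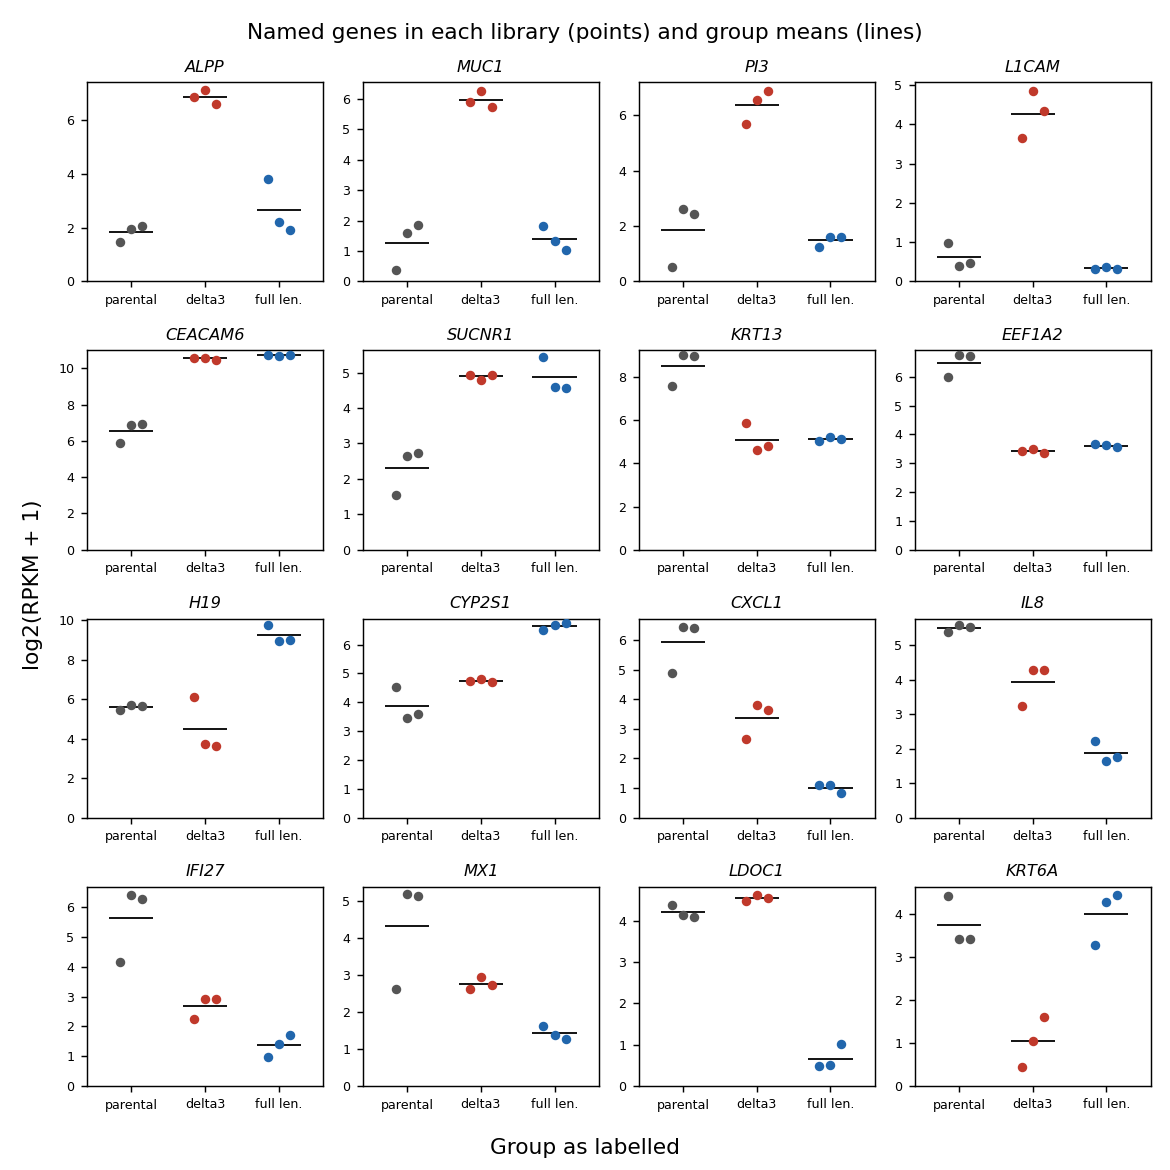
log2(RPKM + 1) of 16 of the genes named for the contrasts, picked by hand from those lists, with 1 point per library and a line at each group mean. ALPP, MUC1, PI3 and L1CAM are higher in the libraries labelled delta3 alone, CEACAM6 and SUCNR1 in those labelled delta3 and the full-length ones, and H19 and CYP2S1 in the full-length group.

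Immune gene lists were higher in the libraries labelled delta3 than in the full-length ones. Of 52 interferon response genes 21 were higher, 0 lower and 31 did not pass (23 and 0 adjusted over the list alone; camera adjusted p = 2.27e-07; adjusted p = 0.364 with an estimated correlation). IFI35 differed by 1.45 log2 units, the immunoproteasome subunits PSMB9 and PSMB8, also in the MHC list, by 1.002 and 0.77, and UBE2L6, an enzyme of ISG15 conjugation, by 0.60. Of 32 genes of NF-kB signalling and inflammatory cytokines 15 were higher, 0 lower and 17 did not pass (17 and 1 adjusted over the list alone; camera adjusted p = 2.24e-05; adjusted p = 0.364 with an estimated correlation). SAA1 and SAA2, near-identical acute-phase genes, differed by 2.70 and 1.33 log2 units, the siderophore-binding LCN2 by 3.28 and complement C3 by 3.72. Of 17 genes of MHC presentation 12 were higher, 0 lower and 5 did not pass (12 and 0 adjusted over the list alone; camera adjusted p = 2.31e-05; adjusted p = 0.364 with an estimated correlation). B2M, the light chain of class I, differed by 0.62 log2 units. Here too most class II members were not tested. Measured against the parental line, the libraries labelled delta3 had 8 interferon genes higher, 18 lower and 26 not passing (10 and 19 adjusted over the list alone; camera adjusted p = 0.181). IFIT1, OASL and ISG20 fell there by 2.24, 1.69 and 1.34 log2 units. Their NF-kB genes went both ways against the parental line, with 8 higher, 12 lower and 12 not passing (8 and 12 adjusted over the list alone; camera adjusted p = 0.879). LCN2 and C3 rose by 2.26 and 3.01 log2 units, and CSF1 and IL1A, a cytokine, fell by 1.31 and 2.41.

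Differentiation lists also separated the libraries labelled delta3 from the full-length ones. Epithelial junction genes were higher in the libraries labelled delta3, with 11 of 32 higher, 1 lower and 20 not passing (14 and 2 adjusted over the list alone; camera adjusted p = 0.000772; adjusted p = 0.474 with an estimated correlation). The claudins CLDN7 and CLDN3 and the protease inhibitor SPINT1 differed by 0.69, 1.36 and 0.90 log2 units. Luminal genes were higher, with 7 of 29 higher, 1 lower and 21 not passing (8 and 1 adjusted over the list alone; camera adjusted p = 0.0247; adjusted p = 0.684 with an estimated correlation), and this list did not pass after quantile normalization (adjusted p = 0.157). TRIM31 and the serine protease TMPRSS2 were higher by 2.42 and 1.91 log2 units, and the epoxygenase CYP2J2 was lower by 0.58 (log2 fold change -0.58). Basal genes were lower, with 12 of 29 lower, 2 higher and 15 not passing (13 and 2 adjusted over the list alone; camera adjusted p = 0.00263; adjusted p = 0.474 with an estimated correlation). PI3 was higher by 4.88 log2 units, and KRT5, SFN and the integrin ITGA6 had log2 fold changes of -1.63, -1.36 and -1.74. Mesenchymal genes were lower, with 5 of 14 lower, 0 higher and 9 not passing (6 and 0 adjusted over the list alone; camera adjusted p = 0.00513; adjusted p = 0.474 with an estimated correlation). Among them the collagen VI chain COL6A1, the metalloproteinase MMP14 and the transcription factor SNAI2 had log2 fold changes of -1.12, -0.75 and -1.88. The mesenchymal list held 30 genes, and VIM, ZEB1, ZEB2, SNAI1 and TWIST1 were among those that missed the expression filter.

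DNA repair and proliferation genes were lower in the libraries labelled delta3 than in the full-length ones. Of 41 nucleotide excision repair genes, 9 were lower, 0 higher and 32 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 0.0252; adjusted p = 0.364 with an estimated correlation). The single-strand binding subunit RPA2 and the DNA ligase LIG1 stood at -0.87 and -0.77 log2 units. Of 46 homologous recombination and Fanconi genes 13 were lower, 1 higher and 32 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 0.000772; adjusted p = 0.364 with an estimated correlation). Its members with the smallest adjusted p were MAD2L2, of translesion synthesis (-0.47 log2 units), and the damage kinase ATM (-0.47). The MAD2L2 call was lost without delta3 replicate 2 or full-length replicate 2 or 3 (adjusted p = 0.0598 to 0.0673), and the ATM call without delta3 replicate 1 or 2 or any 1 full-length replicate (adjusted p = 0.0512 to 0.0891). Of 16 mismatch repair genes 7 were lower, 0 higher and 9 did not pass (10 and 0 adjusted over the list alone; camera adjusted p = 0.00244; adjusted p = 0.364 with an estimated correlation). Its leading members were LIG1 and the polymerase subunit POLD1 (-0.61 log2 units), both also in the excision repair list, and the POLD1 call was lost without delta3 replicate 2 (adjusted p = 0.0508). PCNA and RFC1 to RFC5 are in both of these lists too, and PCNA is also in the proliferation list, so the lists are not separate results. Of 57 proliferation genes 10 were lower, 0 higher and 47 did not pass (5 and 0 adjusted over the list alone; camera adjusted p = 0.000772; adjusted p = 0.452 with an estimated correlation). The spindle checkpoint kinase TTK and thymidylate synthase, TYMS, stood at -0.63 and -0.52 log2 units. Cholesterol synthesis genes were higher, with 4 of 24 higher, 1 lower and 19 not passing (5 and 1 adjusted over the list alone; camera adjusted p = 0.0153; adjusted p = 0.661 with an estimated correlation). FDPS, a farnesyl diphosphate synthase, was higher by 0.69 log2 units, and STARD4, a sterol carrier at -1.27, lost its call without delta3 replicate 1 or 2 or full-length replicate 2 or 3 (adjusted p = 0.0524 to 0.0615).

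In all, 2791 of 11873 genes passed between the libraries labelled delta3 and the full-length ones, 1458 higher and 1333 lower in the former (1472 and 1512 with quantile normalization), and 410 by at least 2-fold (279 higher, 131 lower). The groups did not overlap for 51.2% of genes, where chance gives 10% if all libraries are independent, and more if replicates 2 and 3 are not. The count was 4639 without parental replicate 1, whose spread entered the shared error, and 1281, 1078 and 1041 without delta3 replicate 2, full-length replicate 2 and full-length replicate 3, and 80 with replicates 2 and 3 of each group averaged. With only these 6 libraries and the replicate number as a block, a setting chosen after seeing the data, it was 5091 (2482 higher, 2609 lower), and p53 targets passed as lower (adjusted p = 0.0184). With fry the luminal and cholesterol lists did not pass (adjusted p = 0.295 and 0.183). All 12 lists still passed without parental replicate 1, and p53 targets passed as lower without it (adjusted p = 0.0193, against 0.0581 with it).

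Changes against the parental line were then set side by side. CEACAM6 was raised in both groups, 15.8-fold in the libraries labelled delta3 and 17.8-fold in the full-length libraries, as were SUCNR1, the succinate receptor (6.03 and 5.89-fold), GDA, guanine deaminase (6.50 and 5.80-fold), CEACAM3 (5.82 and 6.81-fold), ITGBL1 (5.23 and 5.46-fold) and S100A4 (6.45 and 13.6-fold). The S100A4 call in the libraries labelled delta3 was lost without delta3 replicate 1 (adjusted p = 0.0509), and without parental replicate 1 its log2 fold change there was 1.92 against 2.69 with it. KRT13 fell in both groups by 10.9 and 10.7-fold, and EEF1A2, a tissue-restricted translation elongation factor, by 8.35 and 7.31-fold. IFI27 fell by 7.62 and 19.2-fold, CXCL1 by 5.89 and 29.8-fold, SPP1, or osteopontin, by 5.48 and 5.46-fold, and SORBS3, an adhesion adaptor, by 5.42 and 6.01-fold. Without parental replicate 1 the log2 fold change of SPP1 was -3.24 in both groups, against -2.45 with it. Altogether 1730 genes passed in both contrasts with the same sign, 696 higher and 1034 lower, and 72 with opposite signs. Independent lists of these sizes would share 213 higher and 338 lower genes.

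Both contrasts use the same parental libraries, whose chance values they share. The covariance of their log2 fold changes across genes was 0.148, against a median of 0.0155 for 1000 simulated pairs of unchanged groups (95% range -0.00486 to 0.160), a difference of 0.132. The correlation was 0.564, against a simulated median of 0.668 (-0.265 to 0.980). In 100 simulated fits the median number of same-sign calls was 0 and the highest 2947, and 1 fit reached the observed number. The observed covariance lay inside its simulated 95% range. The 3 parental libraries cannot be split into sets of 2, so how much of the excess comes from the shared controls stays open. The number of shared genes was 2758 without parental replicate 1. It was 1053, 1036, 1133, 1046 and 1107 without parental replicate 2, parental replicate 3, delta3 replicate 2, full-length replicate 2 and full-length replicate 3.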

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

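The genes of this part were picked after their values were seen, while the tests and the libraries left out were planned. A gene was picked when the libraries labelled delta3 and the full-length libraries had moved in opposite directions against the parental line, each past the threshold, and also differed from each other by limma. This held for 72 genes, 47 higher in the libraries labelled delta3 and lower in the full-length ones, and 25 the reverse. The last condition removed none of the genes called in opposite directions, because opposite calls from the same fit differ by more than either change. A rise of FOXP3 itself was not shown in the libraries labelled delta3, and a small rise was not excluded (ratio of mean RPKM to the parental line 1.70). The 6 with the largest smaller fold change are given, with 4 members of the lists reported above, each as its log2 fold change between the libraries labelled delta3 and the full-length ones.

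HSPB8, a small heat shock protein, stood at 12.2, 29.6 and 4.86 RPKM in the parental, delta3-labelled and full-length libraries (2.33 log2 units), BPGM, an enzyme of red cell glycolysis, at 32.9, 78.9 and 15.5 RPKM (2.245), LCN2 at 222, 1061 and 107 RPKM (3.285), and PRSS8, the protease prostasin, at 12.9, 32.7 and 7.01 RPKM (2.09). SLITRK6, a membrane protein, stood at 26.4, 12.8 and 49.5 RPKM (-1.87) and FGFR2, a growth factor receptor, at 2.30, 0.858 and 4.61 RPKM (-1.59). The claudin CLDN7 (0.69), the immunoproteasome subunit PSMB8 (0.77), and the acute-phase genes SAA1 (2.70) and SAA2 (1.325), which share reads, were higher in the libraries labelled delta3.

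Some of these calls against the parental line were lost without 1 library. In the libraries labelled delta3 this held for HSPB8 (without parental 2 or 3 or delta3 2 or 3, adjusted p = 0.0596 to 0.07), CLDN7 (parental 2 or 3, delta3 1 or 2, adjusted p = 0.0509 to 0.0643), PSMB8 (delta3 2, adjusted p = 0.0723) and SAA1 (parental 2, delta3 2 or 3, adjusted p = 0.0548 to 0.0589). In the full-length libraries it held for HSPB8 (parental 1 or 2, any full-length library, adjusted p = 0.0517 to 0.0915), PRSS8 (parental, delta3 or full-length 2 or 3, adjusted p = 0.0501 to 0.123) and CLDN7 (parental or full-length 2 or 3, adjusted p = 0.0547 to 0.0835). It also held there for PSMB8 (the same 4 libraries, adjusted p = 0.0756 to 0.0855), BPGM (full-length 2 or 3, adjusted p = 0.0628 to 0.0677) and LCN2 (full-length 2 or 3, adjusted p = 0.0501 to 0.0525).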

How the results depend on the processing

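The settings with voom, averaged replicates, the libraries numbered 1 left out, the gene lists without parental replicate 1, and the block for the delta3-labelled and full-length groups alone were chosen after seeing the data. The fit with library weights gave a convergence warning, so its counts carry little weight. Over all settings the FOXP3 contrast of the libraries labelled delta3 with the parental line gave limma adjusted p = 0.0584 to 0.619. Its log2 fold change ran from 0.059 with quantile normalization to 0.845 with a pseudocount of 0.01. The results for named genes took 4998 values over the settings, of which 4803 kept their direction and side of the threshold, 195 kept their direction but lost the call, and 0 reversed. These values come from 216 named results under up to 24 settings, many of which alter the data little. Averaging replicates 2 and 3 of each group kept the call of 108 of the 216 results and lost that of the other 108. The cause of the changes given here was not tested, beyond fewer libraries leaving fewer degrees of freedom.

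For the libraries labelled delta3 against the parental line 4048 genes passed, and 733 with at least 2-fold change. The number was 9357 with library weights, 755 with replicates 2 and 3 of each group as 1 library and 8153 with the libraries numbered 1 left out. Leaving out 1 library gave 2580 (delta3 2) to 5172 (parental 1). For the full-length libraries against the parental line 3190 passed, 350 with at least 2-fold change. It was 9900 with library weights, 1927 with parental 2 and 3 as 1 library, 94 with replicates 2 and 3 of each group as 1 library, 8245 with the libraries numbered 1 left out, and 1704 (full length 2) to 4751 (parental 1) with 1 library left out. Between the delta3-labelled and full-length groups 2791 passed, 410 with at least 2-fold change. It was 9809 with library weights, 80 with 2 and 3 of each group as 1 library, 7487 with the libraries numbered 1 left out, and 1041 (full length 3) to 4639 (parental 1) with 1 library left out. Shared changes numbered 1730, and 6386, 1043, 70 and 5258 under library weights, parental 2 and 3 as 1 library, 2 and 3 of each group as 1 library, and the libraries numbered 1 left out. With 1 library left out they ran from 1036 (parental 3) to 2758 (parental 1). With voom the contrasts gave 4023, 3158 and 2777 genes. Camera with an estimated correlation passed 0, 1 and 0 lists, and 3 lists passed for the libraries labelled delta3 without parental replicate 1.

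With a replicate block over all 9 libraries 4286, 3586 and 3202 genes passed and 1920 were shared, and for the delta3-labelled and full-length groups alone 5091 genes and 13 lists passed. With the block the hypoxia list (adjusted p = 0.124) and the ribosomal list (adjusted p = 0.0526) no longer passed in the libraries labelled delta3, nor the hypoxia list in the full-length ones (adjusted p = 0.052), nor HSPB8 and PRSS8 in the full-length ones. Apart from the p53 list between the delta3-labelled and full-length groups, the block changed no other call among the lists and genes named.

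With fry 9, 10 and 17 lists passed. Lists that passed with fry and not with camera were, in the libraries labelled delta3 against the parental line, nucleotide excision repair (adjusted p = 0.016), MHC presentation (adjusted p = 0.029) and stroma (adjusted p = 0.00617). In the full-length libraries against the parental line they were the FOXP3 targets (adjusted p = 0.0199) and stemness (adjusted p = 0.016). Between the delta3-labelled and full-length groups they were regulatory T cell genes (adjusted p = 0.0336), FOXP3 targets (adjusted p = 0.00277), platinum (adjusted p = 0.0442), stemness (adjusted p = 0.00277), Wnt and Notch (adjusted p = 0.0125), ATF4 (adjusted p = 0.000684) and stroma (adjusted p = 0.00717).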

Other observations

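The tests of this part were chosen after the results were seen, except the gene lists, the gene length test and the search for markers of other cell types.

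Cisplatin resistance is a theme of the series, and untreated cells show only the levels of genes tied to it. ABCC4, an efflux transporter, rose from 2.75 ± 0.382 RPKM in the parental libraries (n = 3) to 11.8 ± 0.667 RPKM in those labelled delta3 and 10.96 ± 0.185 RPKM in the full-length ones. MGST3, a glutathione transferase, and TXNRD1, a thioredoxin reductase, rose by 1.56 and 1.11 log2 units in the libraries labelled delta3, where no rise of FOXP3 was shown. MGST3 and TMEM205, a membrane protein tied to cisplatin resistance, were higher there than in the full-length libraries by 1.31 and 0.56. GSTM2 and GSTM1, close paralogs, fell by 2.55 and 2.47 log2 units in the full-length libraries. The list of platinum transport and thiol detoxification did not pass. Of 38 tested, 11, 5 and 5 were higher, 11, 5 and 3 lower and 16, 28 and 30 not past the threshold in the libraries labelled delta3 against the parental line, the full-length ones against it, and the former against the latter, the order kept here (adjusted over the list alone 12, 5 and 5 higher, 11, 6 and 3 lower; camera adjusted p = 0.676, 0.765 and 0.228).

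Apoptosis regulators of the BCL2 family list (29 tested) had 6, 3 and 6 higher, 4, 1 and 2 lower and 19, 25 and 21 not past the threshold (adjusted over the list alone 6, 0 and 8 higher, 4, 0 and 2 lower; camera adjusted p = 0.336, 0.836 and 0.490). BMF, a pro-apoptotic BH3-only protein, rose by 0.80 log2 units in the libraries labelled delta3, and BIRC3, an inhibitor of apoptosis, rose by 1.26 and stood 1.80 above the full-length libraries. Stemness genes (15 tested) had 4, 3 and 0 higher, 5, 2 and 5 lower and 6, 10 and 10 not past the threshold (adjusted over the list alone 5, 3 and 2 higher, 5, 2 and 5 lower; camera adjusted p = 0.979, 0.267 and 0.124). ITGA6 and NOTCH1, a receptor, fell by 1.81 and 0.90 log2 units in the libraries labelled delta3, and SOX2, a pluripotency factor, rose by 1.71 in the full-length ones, to 2.82 RPKM. Proliferation genes (57 tested) had 5 and 11 higher, 11 and 4 lower and 41 and 42 not past the threshold against the parental line (adjusted over the list alone 5 and 11 higher, 11 and 4 lower; camera adjusted p = 0.172 and 0.335). E2F1, a cell cycle transcription factor, rose by 1.18 and 0.99 log2 units in the 2 groups, TYMS fell by 0.62 in the libraries labelled delta3, and MCM4, of the replicative helicase, rose by 0.65 in the full-length ones. p53 targets (29 tested) had 3, 6 and 1 higher, 8, 2 and 4 lower and 18, 21 and 24 not past the threshold (adjusted over the list alone 3, 6 and 1 higher, 8, 3 and 4 lower; camera adjusted p = 0.546, 0.690 and 0.0581), with CCNG1 and MDM2, targets of p53, rising by 0.57 and 0.56 log2 units in the full-length libraries.

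Lists without a pass in any contrast, in the same order, follow. NRF2 targets (28 tested) had 6, 2 and 5 higher and 0, 2 and 0 lower (adjusted over the list alone 5, 2 and 5, and 0, 1 and 0; camera adjusted p = 0.183, 0.836 and 0.190). Responsive genes of TGF-beta (29) had 5, 3 and 2 higher and 8, 1 and 4 lower (adjusted over the list alone 5, 1 and 2, and 8, 1 and 4; camera adjusted p = 0.636, 0.887 and 0.483). YAP/TEAD targets (23) had 5, 2 and 3 higher and 2, 1 and 3 lower (adjusted over the list alone 5, 0 and 3, and 2, 0 and 3; camera adjusted p = 0.653, 0.637 and 0.991). Wnt and Notch targets (10) had 2, 1 and 1 higher and 3, 1 and 3 lower (adjusted over the list alone 2, 1 and 1, and 3, 1 and 4; camera adjusted p = 0.905, 0.490 and 0.241). MAPK response genes (25) had 5, 3 and 4 higher and 8, 5 and 5 lower (adjusted over the list alone 5, 3 and 4, and 9, 5 and 5; camera adjusted p = 0.905, 0.888 and 0.848). Heat shock genes (22) had 2, 1 and 1 higher and 2, 2 and 4 lower (adjusted over the list alone 1, 1 and 1, and 2, 0 and 5; camera adjusted p = 0.636, 0.888 and 0.350). Oxidative phosphorylation genes (39) had 3, 1 and 3 higher and 6, 9 and 3 lower (adjusted over the list alone 3, 1 and 2, and 6, 9 and 3; camera adjusted p = 0.905, 0.332 and 0.124). Regulatory T cell genes (10) had 0, 1 and 0 higher and 2, 1 and 2 lower (adjusted over the list alone 0, 1 and 0, and 2, 1 and 2; camera adjusted p = 0.636, 0.719 and 0.190).

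Lists that passed in another contrast did not pass in the following. In the libraries labelled delta3 against the parental line these were MHC presentation (6 of 17 higher, 1 lower, with B2M and PSMB9 rising by 0.60 and 0.74 log2 units; 6 and 1 adjusted over the list alone; camera adjusted p = 0.183), nucleotide excision repair (2 of 41 higher, 8 lower; 1 and 7; 0.434), mesenchymal genes (2 of 14 higher, 3 lower; 2 and 3; 0.635), mismatch repair (1 of 16 higher, 3 lower; 1 and 2; 0.905) and homologous recombination (3 of 46 higher, 8 lower; 3 and 8; 0.905). In the full-length libraries against the parental line they were mesenchymal genes (4 of 14 higher, 0 lower, with COL6A1 rising by 1.55 log2 units; 4 and 0 adjusted over the list alone; camera adjusted p = 0.171), nucleotide excision repair (6 of 41 higher, 5 lower; 6 and 5; 0.264), cholesterol synthesis (3 of 24 higher, 2 lower; 0 and 0; 0.559) and epithelial junctions (3 of 32 higher, 6 lower; 3 and 6; 0.822). Between the delta3-labelled and full-length groups they were genes named as FOXP3 targets (1 of 14 higher, 5 lower; 1 and 6 adjusted over the list alone; camera adjusted p = 0.0537), ATF4 (11 of 31 higher, 4 lower; 12 and 4; 0.0645) and histones (0 of 8 higher, 2 lower; 0 and 2; 0.190). The others there were endoplasmic reticulum folding (2 of 20 higher, 1 lower; 2 and 0; 0.489), ribosomal proteins (1 of 58 higher, 7 lower; 1 and 7; 0.618) and hypoxia (3 of 32 higher, 4 lower; 3 and 4; 0.711).

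Median, mean and test differed in sign in some lists that did not pass. These were the platinum, homologous recombination, YAP/TEAD and oxidative phosphorylation lists in the libraries labelled delta3 against the parental line, the BCL2, p53, MAPK and heat shock lists in the full-length ones, and the BCL2, MAPK and stromal lists between the delta3-labelled and full-length groups.

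Markers of other cell types were few. Of the list of fibroblasts and endothelium 5 genes were tested, with 2, 1 and 2 higher and 1, 1 and 0 lower in the 3 contrasts (adjusted over the list alone 2, 1 and 2, and 1, 1 and 0; camera adjusted p = 0.331, 0.637 and 0.400). CDH5, the cadherin of endothelium, stood at 0.108, 4.74 and 0.126 RPKM in the parental, delta3-labelled and full-length libraries and rose by 2.34 log2 units in those labelled delta3. ESAM, an endothelial adhesion molecule, rose by 2.16 and 1.29 log2 units, and LUM, the matrix protein lumican, fell by 2.45 and 1.71, the second call being lost with a pseudocount of 0.01 (adjusted p = 0.0906). Lists of lymphocytes and of myeloid cells had 1 tested gene each, and that of hepatocyte, neural and melanocyte lines had 4, so these were not tested as lists.

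FOXP3 did not pass as higher in the libraries labelled delta3, though a small rise was not excluded (ratio of mean RPKM to the parental line 1.70). A missing exon 3 would leave at least 90.3% of the gene model to collect reads, and the level was 0.414% of that in the full-length libraries, which argues against the missing exon as the cause. A swap among the 9 libraries would need a high value in another group, and the highest FOXP3 outside the full-length libraries was 0.378 RPKM. A swap with a sample from outside, a transgene that was not expressed and a transgene sequence outside the counted gene model were not tested and may each account for it. No biological explanation was tested.

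Parental replicate 1 stood apart from parental replicates 2 and 3. Gene length (rho = -0.0493 across genes) and a swap with another group (0 libraries of the other groups correlated best outside their own) were not borne out, and dilution by RNA of other cells would have lowered the epithelial junction list as much as the uroplakins, where its median difference was -0.2, a fall in itself at percentile 1.55 of matched random lists. RNA of another cell type stayed open, since 3 of 77 markers of other cell types (COL1A1 at 1.76, FAP at 1.54 and NEFL at 2.49 RPKM) reached 1 RPKM in parental replicate 1 alone among the parental libraries. The reverse, in parental replicates 2 and 3 only, held for 1 marker. NEFL also stood at 3.29 to 4.69 RPKM in the full-length libraries and COL1A1 at 1.59 RPKM in full-length replicate 1, so neither was particular to parental replicate 1. Mesenchymal genes (median difference 1.65), YAP/TEAD targets (0.76) and TGF-beta responsive genes (0.473) all lay at the 100th percentile of matched random lists in it, with CTGF at 18.7 RPKM against 0.462 and 0.716 and ANKRD1 at 11.3 RPKM against 0.343 and 0.474. A culture state with raised YAP/TEAD targets was named only after these values were seen and had no independent test, so it stays open beside RNA of another cell type, which the mesenchymal list leaves open too.

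Changes against the parental line were shared by the libraries labelled delta3 and the full-length ones. Shared control libraries alone gave a covariance as large in 30 of 1000 simulations. Without parental replicate 1 this was 0 of 1000, where the covariance was 0.17 against a simulated median of 0.00201. Leaving that library out also removed most of the spread between controls, since the other parental libraries correlated at r = 0.998. The 0 of 1000 therefore cannot limit the part played by shared controls. How much of the overlap the shared controls account for stays open. In the libraries labelled delta3, which held 0.414% of the full-length FOXP3 level, 4048 genes passed, against 3190 in the full-length libraries. This argues against a number of calls that follows the FOXP3 mRNA level as counted. The comparison counts all calls and not the shared ones, and a small rise of FOXP3 was not excluded. It does not settle what underlies the overlap. Selection in G418, which a vector-only library would address, was not tested. Neither was the derivation of the lines, which would need more than 1 derived line per construct. Either may account for shared changes, and the derivation also for differences in each contrast. A shared action of the FOXP3 forms also stayed open and untested.

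Other splits of the 6 libraries of each contrast were counted in limma fits of those libraries alone. With 10 splits the share cannot fall under 0.05, so they are too few. The real splits called 3088, 2829 and 3635 genes and the highest other split called 0 in each contrast, with 1 of 10 splits, the real one, calling as many.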
